A study of Mus musculus with 6 samples.

How the data were processed

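RNA was measured in trunks of mouse embryos at embryonic day 9.5, the piece of the body between the otic vesicle and somite 15 with the forelimb buds. Wild-type embryos were compared with embryos that lack Arid3b, a transcription factor with an AT-rich interaction (ARID) DNA-binding domain. Each group had 3 samples, and per the labels' protocols each sample was RNA pooled from 4 embryos, so that the 6 arrays hold RNA of 24 embryos. The spread between arrays of a group is therefore the spread between pools, not between embryos.

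Per the labels' protocols, total RNA was amplified and labelled with Cy3 for one-colour Agilent arrays. Per the file headers, the spot values came from Agilent Feature Extraction 10.7.3.1 with protocol GE1_107_Sep09 on array design 026655, whose header names the mouse build mm9. The deposited scanner values are intensity values on a linear scale: the processed signal, from which the scanner software had subtracted the background, and the median pixel signal of each spot and of its local background. The deposited value table of the series holds log2 values for 24181 probes. Set against each array's own log2 processed signal it correlated across probes at 0.999 to 1.00 per array. Its 6 columns have medians of 6.77, 6.77, 6.77, 6.77, 6.77 and 6.77 and upper quartiles of 9.14 each, so they had been matched at least at these points. The values are not centred per gene, and the exact method is not given in the sources used here. This table served as an alternative.

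Each array has 44397 spots, of which 43020 are not controls. These hold 39429 probes, 399 of them printed 10 times. Probe accessions, without versions, were matched to gene symbols in a RefSeq gene table of assembly GRCm38.p6. Because that assembly is not the build in the header, it was used only for names and for which genes lie near Arid3b. The match gave 1 symbol for 26424 probes (67.0%), several for 0 and none for 13005, which kept the name in the files. The matched probes cover 20021 gene symbols.

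The main values were log2 of the processed signal minus the 75th percentile of the array's non-control spots. Spots with a non-uniformity or population outlier mark (100 to 169 per array) were set to missing, and spots of 1 probe were averaged. A probe was tested if it was well above background on all 3 arrays of at least 1 group, which left 24420 probes. Each gene was represented by its tested probe with the highest mean over the 6 arrays, which left 19792 genes, 14208 of them with a symbol. Among called genes, 1102 had more than 1 tested probe. Of these, 92 had another probe that moved in the opposite direction, and in 9 that probe passed the test in the opposite direction. Where a probe was not well above background on any array of a group, the difference is a bound. It sets the mean of the brighter group against the dimmer group's mean of, per array, the higher of the probe's own value and the lowest value among probes well above background.

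Genes were tested with lmFit and eBayes of limma 3.58.1 in R 4.3.3, Arid3b-null minus wild type, two-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Every adjusted p of a gene comes from this limma fit. Gene lists were tested with limma's camera at its preset correlation of 0.01, and again with an estimated correlation and with fry, limma's test of whether the genes of a list move one way on balance. The 45 lists were written before the data were examined, and 43 had at least 5 tested genes. Camera and fry took genes with a value on every array. For each list the count of changed members is also given with the adjustment over the list alone. The share of called genes within 10 Mb of Arid3b was compared with that of other genes by a two-sided Fisher's exact test.

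The genes named in the text follow a rule fixed before the data were examined. They are Arid3b; the 12 largest rises and 12 largest falls among called genes with a symbol whose arrays do not overlap between groups; up to 4 called members of each list with the smallest adjusted p, or 2 members where none passed; and Bhlhe40 and Lims2. Genes named outside it are said to have been chosen after their values were seen.

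The fit was tested on simulated data for 19772 genes, in which 67, 67 and 66 genes were given log2 changes of 0.5, 1 and 2. Of these 0%, 61.2% and 87.9% were recovered, and 2.94% of the calls were false. The changed share was far smaller than the 26.5% of genes called in the data. The Benjamini-Hochberg cut-off depends on that share, so these rates do not carry over to the data. Of 40 simulated lists, both changed lists and 0 of the 38 unchanged lists were called. Both changed lists were also called with an estimated correlation. The simulated genes varied independently of each other and without a slide effect. In the data, members of a list can move together, with an estimated correlation of 0.41 for hypoxia and glycolysis genes. The simulation therefore does not test false list calls among correlated genes.

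The file headers put the arrays with the same replicate number on the same slide, 3 slides in all. The deviations of same-numbered arrays from their group means correlated across genes at 0.16, 0.39 and 0.28, all above the limit of 0.1 set for pairing. Wild type replicate 3 and Arid3b-null replicate 1, on different slides, also passed this limit at 0.12, so it does not single out same-numbered arrays. The numbers pair the samples through the shared slide that the headers give. On each of the 3 slides the wild-type array lay at position 1 and the Arid3b-null array at position 2, so that position and group cannot be told apart. No 2 arrays held identical values. Arrays of a group correlated across genes at 0.989 to 0.995, and arrays of different groups at 0.969 to 0.983.

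Between 61.6% and 68.8% of the non-control spots were well above background on an array, and 0 spots were saturated. The number of arrays limits the precision.

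The alternatives fixed before the data were examined were normexp background correction with 75th percentile scaling or quantile normalization, quantile normalization or median scaling of the processed signal, the deposited value table, other filters on dim probes, marked spots kept, the mean of a gene's probes, every probe by itself, trended and robust eBayes, array weights, the slide as a block, other thresholds, each array left out, and other windows around Arid3b. The mean spot signal planned for normexp is not among the columns used here, so the median spot signal took its place. The planned normexp fit stands apart on 2 arrays. On 3 spots of wild type replicate 2 and 9 spots of wild type replicate 3 the local background exceeded the signal by more than 20 units, and the fitted background mean was -47.0 and -657 on these arrays against -3.74 to -6.12 on the others. After seeing the data, both normexp settings were therefore repeated with each array's median background in place of each spot's own, which gave means of -2.83 to -4.49, and the setting with 75th percentile scaling was also repeated with only those 12 spots left out, which gave -4.60 and -4.69 on these arrays. The results of the planned and of the added settings are both given. Folds of single genes under normexp with each array's median background are those with 75th percentile scaling. Every normexp setting adds an offset of 50 units to the corrected signals, which by itself makes the folds of dim genes smaller.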

Results

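Gene expression was measured in the trunks of wild-type and Arid3b-null mouse embryos at embryonic day 9.5, with 3 arrays per group and RNA of 4 embryos on each array. The comparison addresses which transcripts differ in the trunk and forelimb buds when Arid3b is missing. Values are log2 signals relative to each array's 75th percentile, and changes are Arid3b-null minus wild type. The 75th percentile of the processed signal lay between 611 and 844 units on the 6 arrays.

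Arid3b itself fell in the Arid3b-null trunks on each of its 3 probes. The brightest probe read 2.24 ± 0.31 (SD, n = 3) in wild type and 0.55 ± 0.10 (SD, n = 3) in Arid3b-null, a log2 change of -1.69 ± 0.17 (SE, limma adjusted p = 0.00154), which leaves 31.0% of the wild-type signal. The within-slide changes were -1.63, -1.92 and -1.51. Another probe changed by -3.23 ± 0.20 (SE), leaving 10.6%, and the dimmest by -1.90 ± 0.18, leaving 26.9%. These 2 probes were well above background on 2 of the 3 Arid3b-null arrays. Where the probes lie relative to the deleted part of the gene is not given in the sources used here, so the remaining signal cannot be assigned to a transcript.

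**Figure D1:**
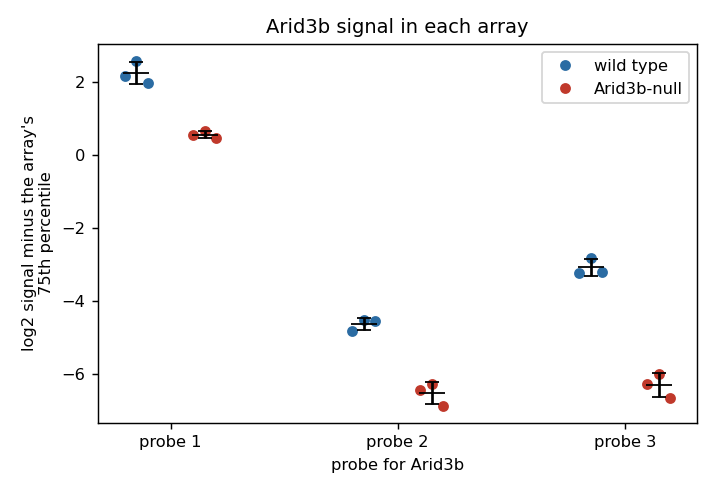
Signal of the 3 Arid3b probes on each array, as log2 relative to the array's 75th percentile. Points are arrays, horizontal marks are group means and bars are SD (n = 3 per group); on each probe all 3 Arid3b-null arrays lie below all 3 wild-type arrays.

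The largest rises in the Arid3b-null trunks included genes of glycolysis and genes induced by hypoxia. Eno2, which encodes an enolase of glycolysis, rose by 5.14 ± 0.12 (log2, SE), or 35.2-fold. Chac1, a glutathione-degrading enzyme induced in the unfolded protein response, rose 27.0-fold, Ndufa4l2, a mitochondrial protein induced by hypoxia, 18.0-fold and Ndrg1, another hypoxia-induced gene, 16.3-fold. The next rises were Nrn1 at 16.0-fold, Bhlhe40 at 15.2-fold, Adm2 at 15.1-fold, Ier3 at 14.2-fold, the amino acid transporter gene Slc7a3 at 12.2-fold, the phosphofructokinase gene Pfkp at 11.5-fold and Rora at 11.2-fold. Adm2 was well above background on 1 of 3 wild-type arrays. Wdr64, not well above background in wild type, was at least 2.60-fold higher. Under normexp with each array's median background the rises were smaller, Eno2 at 21.6-fold, Chac1 at 17.1-fold, Pfkp at 7.22-fold, Bhlhe40 at 6.88-fold, Ier3 at 6.22-fold, Slc7a3 at 6.05-fold, Rora at 4.28-fold, Nrn1 at 4.24-fold, Adm2 at 3.08-fold and Wdr64 at 1.53-fold, below its bound.

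Among the falls, Gcg, which encodes preproglucagon, was not well above background in Arid3b-null and was at least 33.3-fold lower (limma adjusted p = 2.35e-05). Serpina6, a plasma corticosteroid-binding protein, fell 19.5-fold, Lhx3, a motor neuron and interneuron transcription factor, 12.6-fold and Gsx1, a dorsal neural tube factor, 11.8-fold. C1qtnf3 fell 10.3-fold, the neuronal transcription factor Nhlh2 9.94-fold and Scrt1 8.80-fold, and Mstn, which encodes myostatin, had a log2 change of -3.42. Serpina6, Gsx1 and Mstn were well above background on 1 of the 3 Arid3b-null arrays and C1qtnf3 on 2. Vxn, Tal2, Ttc9b and Slc9b1 were not well above background in Arid3b-null and were at least 4.22-fold, 3.25-fold, 4.39-fold and 2.01-fold lower. The Serpina6 fall was 11.8-fold without Arid3b-null replicate 1 and 31.7-fold without Arid3b-null replicate 2. Under normexp with each array's median background Gcg fell 5.04-fold, Lhx3 4.76-fold, Scrt1 4.12-fold, Nhlh2 3.70-fold, C1qtnf3 2.94-fold, Serpina6 2.42-fold, Gsx1 1.57-fold, Mstn 1.56-fold, Ttc9b 1.52-fold, Vxn 1.43-fold and Tal2 1.33-fold, and Slc9b1 did not pass (adjusted p = 0.278), so the bounds hold only for the main scale. Of 172 called genes that the naming rule covers, Arid3b among them, 50 had folds smaller by more than 1.5 times in that setting.

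**Figure D2:**
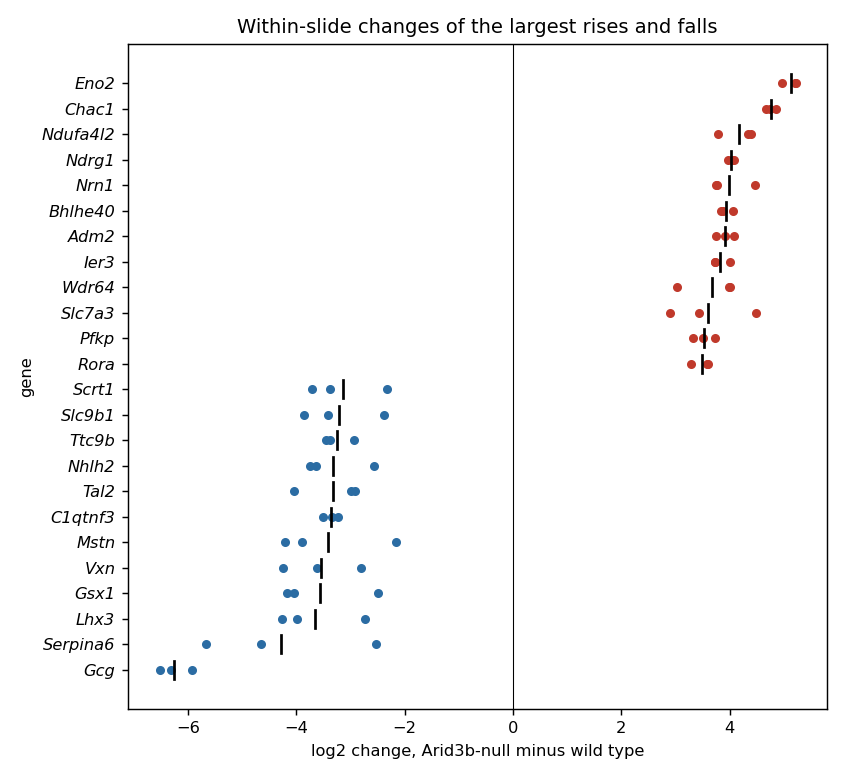
Within-slide log2 changes (Arid3b-null minus wild type) of the 12 largest rises and 12 largest falls; points are the 3 slides and vertical marks the fitted change. Eno2 heads the rises at 5.14 and Gcg the falls. No gene changes sign between slides, which follows from choosing genes whose arrays do not overlap between groups. For Wdr64, Gcg, Vxn, Tal2, Ttc9b and Slc9b1, below background in 1 group, the marks are fitted values that exceed the measured bound.

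Of 19792 genes tested, 2694 rose and 2560 fell in Arid3b-null (limma, Benjamini-Hochberg), 26.5% in all. The change was at least 2-fold for 732 of the genes that rose and 564 of those that fell. In 9135 genes (46.2%) the arrays of the groups did not overlap, where chance gives 10%. Every called gene with a value on all slides changed in the fitted direction on each of the 3 slides. This adds no separate support, since 5253 of the 5254 called genes had arrays that did not overlap between groups. For these the direction on each slide was fixed. Under the planned normexp correction with 75th percentile scaling 2 genes rose and 0 fell. With only 12 spots of wild type replicates 2 and 3 left out of that fit it was 2309 and 2169, and with each array's median background 2351 and 2187. Without a filter on dim probes 1288 rose and 998 fell, without wild type replicate 1 it was 1661 and 1211, without Arid3b-null replicate 2 it was 1752 and 1626, and the falls were 1622 without wild type replicate 2 and 1425 without Arid3b-null replicate 3.

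Hypoxia and glycolysis genes rose together. Of 39 members measured, 36 rose and 0 fell (37 and 0 adjusted over the list alone), with a median log2 change of 1.80 and within-slide medians of 1.85, 1.82 and 1.80. Besides Ndrg1, Pfkp and Bhlhe40, a repressor of transcription and clock component, Ero1a, the oxidase of protein folding in the endoplasmic reticulum, rose 6.21-fold (3.64-fold under normexp with each array's median background). The list was called higher (camera adjusted p = 1.44e-24), a call not kept with an estimated correlation (adjusted p = 0.411 with an estimated correlation). None of the 20 called lists kept its call with an estimated correlation, where the smallest adjusted p was 0.402 with an estimated correlation. The neural tube progenitor list had an estimated correlation of 0.010, about the preset, yet its unadjusted camera p went from 2.60e-06 to 0.00936. The lost calls therefore cannot be put down to correlation among members alone.

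Genes of the integrated and endoplasmic reticulum stress responses were called higher as a list, 18 of 33 members up and 3 down (18 and 4 adjusted over the list alone, median 0.61, camera adjusted p = 2.40e-05, adjusted p = 0.597 with an estimated correlation). Beside Chac1, Stc2 rose 8.12-fold, Vldlr, a lipoprotein receptor, 7.32-fold and Ddit3, the CHOP transcription factor, 4.40-fold. The p53 target list was not called (camera adjusted p = 0.051), with 8 members up and 5 down of 29 (8 and 5 adjusted over the list alone), Sesn2 at 2.94-fold among them. It was called higher without wild type replicate 2 or Arid3b-null replicate 1 or 3 (adjusted p = 0.0421, 0.0383 and 0.0369), in the deposited value table (0.0208), without a filter on dim probes (0.00455), with the mean of a gene's probes (0.0478) and with fry (0.0223). Immediate early and dissection stress genes went both ways, 10 up and 5 down of 28 (12 and 7 adjusted over the list alone, camera adjusted p = 0.138). Atf3 rose 2.61-fold and Nr4a1 2.10-fold, while Gadd45g fell 2.23-fold.

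Transcripts of early neurons fell as a list. Of 37 members 32 fell and 1 rose (33 and 1 adjusted over the list alone), with a median log2 change of -1.69, or -1.46 with genes below background at their bound, and within-slide medians of -1.70, -1.25 and -1.82. The list median was smallest, -0.87, under the planned normexp correction with quantile normalization. The intermediate filament genes Ina and Nefl fell 6.87-fold and 4.12-fold, the RNA-binding protein gene Elavl3 6.97-fold, and Slc18a3, the vesicular acetylcholine transporter of motor neurons, 6.37-fold (3.51-fold under normexp with each array's median background). The list was called lower (camera adjusted p = 1.01e-17, adjusted p = 0.411 with an estimated correlation). The neural tube progenitor list was called lower, 15 down and 1 up of 31 (16 and 3 adjusted over the list alone, median -0.62, camera adjusted p = 2.23e-05, adjusted p = 0.402 with an estimated correlation). Among them Dbx1 fell 7.91-fold, Fabp7 2.83-fold and Dbx2 2.48-fold, the Dbx genes being homeobox factors of dorsoventral domains of the neural tube.

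Cholesterol synthesis genes fell, 18 of 24 down and 0 up (19 and 1 adjusted over the list alone, median -0.70, camera adjusted p = 9.28e-08, adjusted p = 0.411 with an estimated correlation). Msmo1 fell 2.59-fold and Idi1 2.53-fold. The oxidative phosphorylation list was called lower, with 12 of 53 members down, 0 up and 41 not passing (12 and 0 adjusted over the list alone, median -0.29, camera adjusted p = 2.42e-05, adjusted p = 0.618 with an estimated correlation), Cycs, the cytochrome c gene, by 2.03-fold, Ndufa5 by 1.65-fold and Cox5a by 1.52-fold. Ndufa5 and Cox5a did not pass without a filter on dim probes (adjusted p = 0.0622 and 0.0545). The S phase list was called lower, with 10 down, 1 up and 24 not passing of 35 (11 and 1 adjusted over the list alone, median -0.26, camera adjusted p = 0.00112, adjusted p = 0.597 with an estimated correlation), with Rrm2 1.97-fold, E2f2 1.96-fold, Ccne1 1.85-fold and Fen1 1.74-fold lower. The list of G2 and M phase was not called (2 up and 2 down of 35, 0 and 0 adjusted over the list alone, camera adjusted p = 0.186). The tests of oxidative phosphorylation and S phase turned higher under the planned normexp correction with 75th percentile scaling (adjusted p = 0.194 and 0.900). The primitive erythroid list was called lower, with 9 down, 0 up and 23 not passing of 32 (10 and 0 adjusted over the list alone, median -0.35, camera adjusted p = 0.000171, adjusted p = 0.597 with an estimated correlation), among them Klf1, the erythroid transcription factor, by 2.74-fold, Cited4 by 2.33-fold, Bpgm by 2.13-fold and Gata1 by 1.76-fold.

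In the surface epithelium list 20 members rose and 1 fell of 30 (22 and 1 adjusted over the list alone, median 0.70, camera adjusted p = 3.81e-07, adjusted p = 0.546 with an estimated correlation), led by Krt19 at 4.96-fold, with Rab25 at 2.29-fold, Tfap2a at 2.26-fold and Wnt6 at 1.68-fold. In the list of the apical ectodermal ridge (the signalling ectoderm at the limb bud's edge) and limb ectoderm 7 members rose and 0 fell of 19 (7 and 1 adjusted over the list alone, median 0.30, camera adjusted p = 0.0106, adjusted p = 0.597 with an estimated correlation). Jag2 rose 2.68-fold, Fgf9 2.10-fold and Dlx5 1.86-fold, the last not passing without a filter on dim probes (adjusted p = 0.0554).

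Retinoic acid, Wnt, FGF and BMP lists were called higher. Of 22 retinoic acid pathway genes 9 rose and 1 fell (12 and 1 adjusted over the list alone, median 0.46, camera adjusted p = 0.000217, adjusted p = 0.526 with an estimated correlation), among them Cyp26b1 and Cyp26a1, which degrade retinoic acid, at 3.13-fold and 2.01-fold, and Dhrs3 at 2.38-fold. Of 19 canonical Wnt targets 9 rose and 1 fell (10 and 1 adjusted over the list alone, median 0.52, camera adjusted p = 0.000664, adjusted p = 0.546 with an estimated correlation), with Sp5 up 2.30-fold, Rnf43 up 2.05-fold and Ccnd1 down 1.57-fold. Of 16 genes of feedback in the FGF pathway 6 rose and 0 fell (7 and 0 adjusted over the list alone, median 0.38, camera adjusted p = 0.00324, adjusted p = 0.597 with an estimated correlation), Spred3 by 2.01-fold and Dusp5 by 1.95-fold, each well above background on 2 of 3 wild-type arrays and neither passing under normexp with each array's median background (adjusted p = 0.106 and 0.111). The 19 BMP targets were called higher (6 up, 1 down, the same adjusted over the list alone, median 0.24, camera adjusted p = 0.0472, adjusted p = 0.618 with an estimated correlation), with Grem1 up 1.93-fold, Msx1 up 1.65-fold and Id4 down 2.50-fold (1.65-fold under normexp with each array's median background). The BMP call was lost without wild type replicate 1 or 3 or Arid3b-null replicate 1 or 2 (adjusted p = 0.0701, 0.0774, 0.0573 and 0.0922) and with median scaling (0.0524), and Msx1 did not pass without a filter on dim probes (0.0551).

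The extracellular matrix list was called higher, with 13 up, 0 down and 27 not passing of 40 (14 and 1 adjusted over the list alone, median 0.25, camera adjusted p = 0.000581, adjusted p = 0.597 with an estimated correlation). The laminin genes Lama5 and Lamb1 rose 2.50-fold and 2.33-fold and the nidogen gene Nid2 2.12-fold. The list of integrin-linked and focal adhesion genes was called higher, with 9 up, 0 down and 19 not passing of 28 (11 and 0 adjusted over the list alone, median 0.36, camera adjusted p = 0.000664, adjusted p = 0.597 with an estimated correlation), Itga8 by 2.04-fold and Pxn by 1.84-fold. Intermediate mesoderm genes were called higher, 5 up and 1 down of 17 (8 and 1 adjusted over the list alone, median 0.33, camera adjusted p = 0.0265, adjusted p = 0.449 with an estimated correlation), with Ret 1.76-fold and Osr1 1.43-fold higher, Osr1 not passing without a filter on dim probes (adjusted p = 0.0573). Ribosomal protein genes were called higher (median 0.19, camera adjusted p = 0.000803, adjusted p = 0.717 with an estimated correlation), but of 54 members only Rpl3, at 1.33-fold, passed the test (0 adjusted over the list alone), and the within-slide medians were 0.40, 0.23 and -0.05. This median was -0.06 in the deposited value table and 0.03 after quantile normalization, and the call was lost in both, and with fry (adjusted p = 0.171). The single call of Rpl3 was lost whichever array was left out and with the slide as a block (adjusted p = 0.0539).

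**Figure D3:**
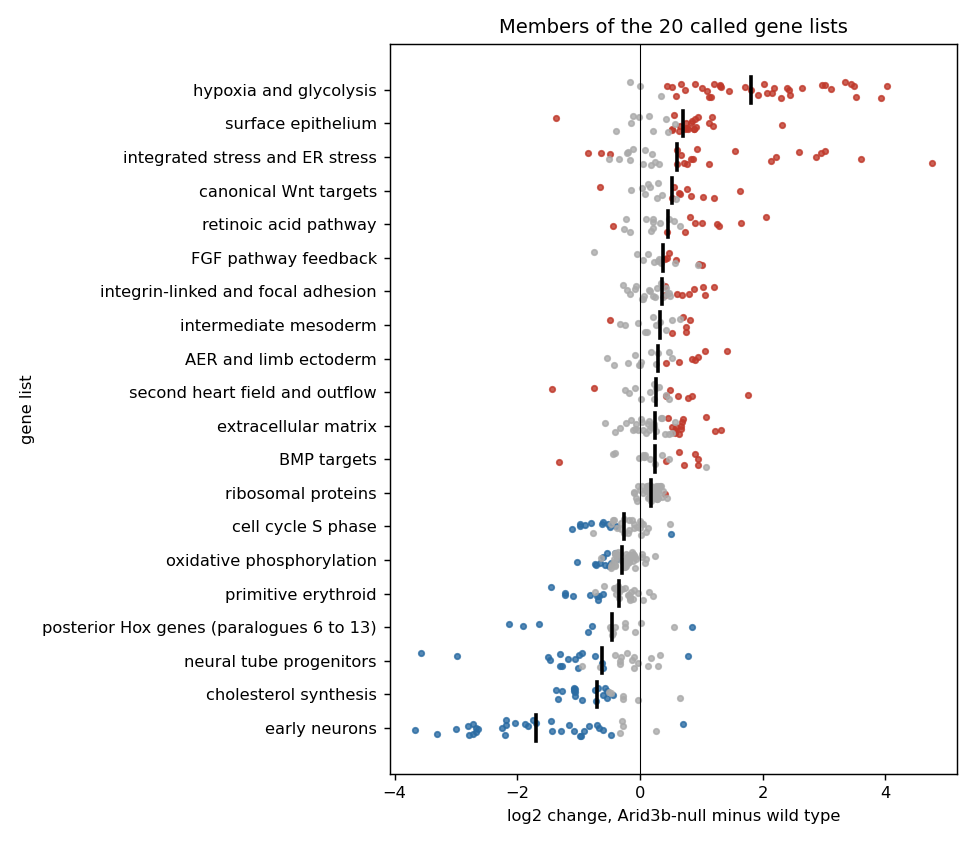
Log2 changes (Arid3b-null minus wild type) of the members of the 20 gene lists called by camera with its preset correlation. Each point is a gene, coloured if it passed the test and grey if not, and the vertical mark is the list's median, from 1.80 for hypoxia and glycolysis to -1.69 for early neurons.

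The second heart field and outflow list, genes of the progenitors that lengthen the heart tube, was called higher, but its leading member fell. Isl1, a transcription factor of these progenitors that is also made by motor neurons, fell 2.69-fold, while Fgf15 rose 3.39-fold, Fgf10 1.79-fold and Nrp2 1.73-fold. In all 6 members rose and 2 fell of 19 (7 and 2 adjusted over the list alone, median 0.26, camera adjusted p = 0.0345, adjusted p = 0.597 with an estimated correlation). The call was lost without wild type replicate 1 or 3 or Arid3b-null replicate 2 (adjusted p = 0.0629, 0.0774 and 0.0922), with median scaling (0.0507), in the deposited value table (0.0693) and under the planned normexp correction with 75th percentile scaling (0.0915). Of 2 genes fixed beforehand from earlier work on Arid3b mutant hearts, Bhlhe40 rose 15.2-fold and Lims2, an adaptor of integrin adhesions, 1.53-fold (limma adjusted p = 0.0227, both also adjusted over the list alone). The Lims2 call was lost without any 1 of the wild-type arrays or Arid3b-null replicate 3 (adjusted p = 0.0717, 0.0640, 0.0622 and 0.0599), in the deposited value table (0.0600) and without a filter on dim probes (0.0855). Cardiac muscle genes were not called as a list (1 up and 3 down of 29, 0 and 0 adjusted over the list alone, median -0.21, camera adjusted p = 0.266), though they were called lower without Arid3b-null replicate 3 (adjusted p = 0.0369).

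The list of posterior Hox genes, those of paralogue groups 6 to 13, was called lower, with 5 down, 1 up and 10 not passing of 16 (the same adjusted over the list alone, median -0.45, camera adjusted p = 0.0265, adjusted p = 0.688 with an estimated correlation). Hoxa11 fell 4.39-fold, Hoxd10 3.74-fold and Hoxa10 3.11-fold, while Hoxb9 rose 1.80-fold but did not pass without a filter on dim probes (adjusted p = 0.0528). Under normexp with each array's median background the 3 falls were 2.46-fold, 2.23-fold and 1.56-fold. The within-slide medians were -0.06, -0.40 and -0.68. The call was lost without Arid3b-null replicate 2 (adjusted p = 0.143), with array weights (0.0566), under the planned normexp correction with 75th percentile scaling (0.0604) and with fry (0.0633). The limb bud mesenchyme list, which shares these 3 falling genes, was not called (3 up and 6 down of 28, 4 and 6 adjusted over the list alone, median 0.01, camera adjusted p = 0.941), and its Lhx9 fell 2.73-fold. Anterior Hox genes were not called either (3 up and 3 down of 15, 5 and 4 adjusted over the list alone, camera adjusted p = 0.437).

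In several lists that were not called, members moved in opposite directions, some of them strongly. In the Notch pathway (2 up and 7 down of 22, 3 and 7 adjusted over the list alone, camera adjusted p = 0.393) the target genes Heyl and Nrarp fell 6.51-fold and 2.82-fold and the ligand gene Dll3 3.54-fold, while Jag2 rose. Fry called the Notch list lower (adjusted p = 0.00175). In the endothelium (11 up and 6 down of 39, 15 and 7 adjusted over the list alone, camera adjusted p = 0.0568) the connexin genes Gja5 and Gja4 fell 6.49-fold and 1.84-fold, while Sox17 and Acvrl1 rose 2.31-fold and 2.26-fold. The endothelium list was called with the slide as a block (camera adjusted p = 0.0436, adjusted p = 0.511 with an estimated correlation), without wild type replicate 2 or Arid3b-null replicate 1 (0.0254 and 0.0496), and under several other filters, probe choices and normalizations. In the somite and sclerotome list (2 up and 5 down of 23, the same adjusted over the list alone, camera adjusted p = 0.941) the sclerotome genes Pax1 and Pax9 fell 3.86-fold and 2.46-fold, while Tbx6, of presomitic mesoderm, rose 3.15-fold. In the skeletal myogenic list (2 up and 5 down of 20, 3 and 5 adjusted over the list alone, camera adjusted p = 0.711) Myog fell 1.93-fold and Chrna1, well above background on 2 of 3 Arid3b-null arrays, 2.85-fold. In the neural crest and glia list (9 up and 7 down of 24, 11 and 7 adjusted over the list alone, camera adjusted p = 0.107) Kit rose 2.18-fold and Foxd3 2.10-fold, while Fabp7 fell. Under normexp with each array's median background Gja5 fell 3.22-fold, Heyl 3.14-fold, Nrarp 1.87-fold and Chrna1 1.35-fold.

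Markers of other tissues and of the parts next to the dissected piece also moved both ways. In the gut endoderm, liver and lung list 7 rose and 13 fell of 33 (10 and 14 adjusted over the list alone, camera adjusted p = 0.540), Krt19 up and Serpina1a down 2.57-fold. Of 17 genes of the macrophage and leukocyte list, which includes platelet genes, 5 rose and 5 fell (5 and 6 adjusted over the list alone, camera adjusted p = 0.540). The platelet genes Itga2b and Pf4 rose 3.09-fold and 2.64-fold. Cx3cr1 fell 7.76-fold (well above background on 1 of 3 Arid3b-null arrays) and Coro1a 2.12-fold. The list's other called members were looked up after the values were seen. The platelet genes Ppbp and Gp9 rose, as did Aif1 (limma adjusted p = 0.0486). Mpo, Tyrobp and Cd52 fell, Tyrobp being well above background on 2 and Cd52 on 1 of 3 Arid3b-null arrays. Aside from Aif1, the rises were thus of platelet genes. In the yolk sac and extraembryonic list 4 rose and 5 fell of 24 (5 and 6 adjusted over the list alone, camera adjusted p = 0.925), Ascl2 up 7.45-fold and Ttr down 2.14-fold. The otic vesicle list had 7 up and 3 down of 13 (the same adjusted over the list alone, camera adjusted p = 0.138), with Neurod1 3.35-fold lower, and was called higher without Arid3b-null replicate 3 (0.0360) or a filter on dim probes (0.0104). The head and midbrain list had 2 up and 3 down of 14 (2 and 4 adjusted over the list alone, camera adjusted p = 0.640), and the tail bud list 5 up and 4 down of 17 (the same adjusted over the list alone, camera adjusted p = 0.529), with Fst 2.48-fold higher and the list called higher by fry (adjusted p = 0.0396). Under normexp with each array's median background Ascl2 rose 4.42-fold and Itga2b 1.77-fold, and Neurod1 fell 1.86-fold and Cx3cr1 1.47-fold.

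The remaining lists were not called. The pharyngeal arch list had 7 up and 2 down of 30 (8 and 2 adjusted over the list alone, camera adjusted p = 0.262), Fgf15 up and Pax1 down. The list of cadherins and cell movement had 6 up and 4 down of 39 (8 and 4 adjusted over the list alone, camera adjusted p = 0.138, called higher without a filter on dim probes at 0.0490 and under the planned normexp correction with 75th percentile scaling at 0.00538), with Cdh13, an atypical cadherin, 2.68-fold higher. The Hedgehog pathway had 4 up and 4 down of 20 (5 and 4 adjusted over the list alone, camera adjusted p = 0.941), the target Gli1 up 1.51-fold and the co-receptor Cdon up 1.70-fold. Imprinted genes had 5 up and 3 down of 27 (the same adjusted over the list alone, camera adjusted p = 0.458), the maternally expressed RNA Meg3 up 2.04-fold and Nnat down 1.83-fold. Apoptosis genes had 3 up and 5 down of 21 (the same adjusted over the list alone, camera adjusted p = 0.689), with Hrk, which promotes cell death, 3.24-fold higher and Cycs lower. In the ARID family (2 up and 1 down of 13, the same adjusted over the list alone, camera adjusted p = 0.529) Arid3b fell and Kdm5b and Jarid2 rose 1.65-fold and 1.59-fold. Without wild type replicate 1 both rises lost their call (adjusted p = 0.0544 and 0.0652), as did that of Jarid2 without wild type replicate 2 (0.0530). Neither passed without a filter on dim probes (0.0590 and 0.0693), nor did Gli1 (0.0540). For the skeletal myogenic, Notch and limb bud mesenchyme lists the median was above 0 and the mean and test below it. The somite list's median and test lay above 0 and its mean below, and the tests of the yolk sac and Hedgehog lists lay above 0 with medians and means below. Among 4 tested sex-linked genes, Eif2s3y, on the Y chromosome, was 1.90-fold higher in the Arid3b-null pools (limma adjusted p = 0.0294), and Xist, the RNA of the inactive X chromosome, did not pass (-0.21 ± 0.31, SE). The Eif2s3y call was lost without wild type replicate 1 or 2 or Arid3b-null replicate 1 or 2 (adjusted p = 0.0938, 0.0863, 0.0827 and 0.0889), with the slide as a block (0.0640), in the deposited value table (0.0546) and without a filter on dim probes (0.0948). The readings by slide were looked up after the values were seen. On slides 1 and 2 Eif2s3y and the Y-linked Ddx3y and Kdm5d read higher in Arid3b-null, and Xist lower. On slide 3 Xist read higher in Arid3b-null (-0.79 against -1.58), and Ddx3y and Kdm5d lower. Ddx3y and Kdm5d did not pass (limma adjusted p = 0.304 and 0.0693). The pools thus were not shown to be balanced for sex, and the sex-linked signal differed by slide.

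Genes close to Arid3b on its chromosome were examined because a null allele can carry flanking chromosome of the strain in which it was made. Within 10 Mb of Arid3b in assembly GRCm38.p6, 62 of 183 tested genes were called (33.9%), against 4074 of 14024 other genes (29.1%). The odds ratio was 1.25 (95% confidence interval 0.90 to 1.72, two-sided Fisher's exact p = 0.164). It passed the threshold in a window of 20 Mb (odds ratio 1.31, Fisher's exact p = 0.0335), without a filter on dim probes (1.53, p = 0.0359), with every probe by itself (1.35, p = 0.0269) and with trended and robust eBayes (1.35, p = 0.0473).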

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

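The normexp settings with each array's median background and with 12 spots left out were added after seeing the data, all others fixed before. The fall of Arid3b kept its direction in every setting and its side of the threshold in all but normexp with 75th percentile scaling (log2 change -1.38, adjusted p = 0.298, range over all settings 0.000179 to 0.298). In that planned setting 2 genes rose and 0 fell, 100% of the calls being rises against 51.3%, 3 lists were called lower, and the median change of all genes was -0.22 against -0.04. The 1st percentile of its corrected signal was 96.9 and 752 on wild type replicates 2 and 3 against 54.7 to 55.1 on the other arrays. With only the 12 spots left out, 2309 genes rose and 2169 fell and 4078 of the 5254 calls remained, so these spots account for most of the loss. With each array's median background it was 2351 and 2187, and 4124 calls. Without a filter on dim probes, where 32530 genes were tested, 1288 rose and 998 fell and the odds ratio near Arid3b was 1.53. Of the genes that the rule names 36 lost their call there. In it the lists of cadherins, immediate early genes and neural crest were also called higher (adjusted p = 0.0490, 0.0382 and 0.0426). At 1.5-fold or more 1578 genes fell. The odds ratio passed the threshold at 1.35 with every probe by itself, 1.35 with trended and robust eBayes and 1.31 in the 20 Mb window; the cause was not tested. With an estimated correlation 0 lists were called higher and 0 lower, against 14 and 7 with fry. Fry did not call the ribosomal protein and posterior Hox lists, and did call p53 targets and tail bud higher and Notch lower. Leaving out 1 array gave 1661 to 2018 rises and 1211 to 2024 falls, with fewer samples in the fit. With the replicate block, which is the slide, 2428 genes rose and 2348 fell, 4269 of the calls remained, and 1 list call, endothelium, changed; of the genes that the rule names 7 lost their call, among them Ttk (adjusted p = 0.0662), Rpl3 and Eif2s3y.

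Under normexp with 75th percentile scaling 18 named genes that had risen took the opposite sign, none of them past the threshold: Wdr64 (-0.55), Lims2 (-0.0046), Dlx5 (-0.28), Sp6 (-0.19), Spred3 (-0.72), Dusp5 (-0.71), Dkk4 (-0.48), Slc39a5 (-0.84), Pax8 (-0.19), Fgf3 (-0.76), Dmbx1 (-0.77), Polk (-0.12), Ttk (-0.19), Hjurp (-0.13), Pxn (-0.26), Fermt3 (-0.28), Slc22a18 (-0.11) and Itga2b (-0.14). So did the tests of the lists of oxidative phosphorylation (median 0.0010) and S phase (-0.010). The lists of canonical Wnt targets, primitive erythroid genes, limb ectoderm, intermediate mesoderm, posterior Hox genes and second heart field lost their call in that setting, and the cadherin list was called higher (adjusted p = 0.00538). The ribosomal protein list turned in the deposited value table (median -0.064). Leaving out each array in turn, 146 of 171 called genes that the rule names beside Arid3b and 17 of 20 called lists kept their call throughout. Under the 16 other settings 2 genes and 10 lists kept it, or 127 and 16 with the planned normexp with 75th percentile scaling set aside. These 16 do not count the estimated correlation, with which 0 lists were called, or fry, which did not call the ribosomal protein and posterior Hox lists. Signal over background limits dim genes: 56 genes were not well above background on any wild-type array and 51 on any Arid3b-null array, so their folds are bounds.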

Other observations

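The gene groups in this paragraph and the next were assembled after the values had been seen, from textbook markers, and were not tested as sets. Their folds and bounds are on the main scale only. Other genes near background had much smaller folds under normexp with each array's median background. Genes of the pancreas and of hormone-producing gut cells were mostly lower in Arid3b-null: 15 of 25 measured members fell and 1 rose (15 and 3 adjusted over the list alone). Besides Gcg, Chga fell 4.75-fold, Insm1 4.32-fold, Ghrl 3.19-fold and Sst 2.86-fold, and Ptf1a, a transcription factor of the pancreas and dorsal neural tube, was not well above background in Arid3b-null and was at least 4.72-fold lower. Several of these genes, Insm1 and Isl1 among them, are also made by neurons. Plasma proteins of the liver showed 15 falls and 0 rises among 25 (16 and 1 adjusted over the list alone), Alb at 7.51-fold (well above background on 2 of 3 Arid3b-null arrays, and 3.71-fold without Arid3b-null replicate 1), Fgg at 4.52-fold, Afp at 2.72-fold and Vtn at 2.31-fold. Genes of noradrenergic and autonomic neurons showed 9 falls and 2 rises among 16 (9 and 3 adjusted over the list alone). Dbh, which makes noradrenaline, fell 8.71-fold and was well above background on 2 of 3 Arid3b-null arrays, while Ret rose.

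Of 17 megakaryocyte and platelet genes 10 rose and 0 fell (11 and 0 adjusted over the list alone), among them Itga2b, Ppbp at 2.76-fold, Gp6 at 2.54-fold and Treml1 at 2.13-fold. Of 21 myeloid and progenitor genes 7 fell and 3 rose (8 and 4 adjusted over the list alone), with Jaml at 4.76-fold, Myb at 3.78-fold, Tyrobp at 3.46-fold and Mpo at 2.53-fold lower (Tyrobp well above background on 2 of 3 Arid3b-null arrays). Genes of arterial endothelium went both ways, 6 up and 3 down of 18 (the same adjusted over the list alone). Heyl, Gja5 and Gja4 fell, and Dll4, Sox17 and Edn1 rose 2.14-fold, 2.31-fold and 2.04-fold.

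Tests chosen only after the results were seen are those of array position, handling, the neural share, and neuron against progenitor genes. Of the 10 splits of the 6 arrays into 3 and 3, 1, the real one, gave as many called genes as the 5254 seen. Each of the others gave 0 (highest 0), but 10 splits are too few for a share under 0.05. The others also mix wild-type and Arid3b-null arrays, so any large difference between the groups widens their spread and lowers their calls. Their counts therefore say nothing on the cause of that difference. The wild-type array lay at the first position on 3 of 3 slides, so position and genotype cannot be told apart for changes that the genotype label does not itself predict. Arid3b, which the label does predict to fall, fell on each slide (-1.63, -1.92 and -1.51).

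The rise of hypoxia and glycolysis genes was weighed against 3 technical explanations. Scaling between arrays is argued against by the list's median, which lay between 1.55 and 1.93 under all 6 normalizations planned. A smaller neural share that raises all other tissues is argued against too, since the hypoxia median exceeded that of somite and limb mesenchyme genes (0.039) by 1.77 (95% bootstrap interval 1.16 to 2.24). The bootstrap intervals here and in the next paragraph reflect spread among the genes of a list, not between pools. Within slides the hypoxia medians were 1.85, 1.82 and 1.80. Those of somite genes were 0.10, -0.19 and 0.09, and those of limb mesenchyme genes 0.14, 0.09 and -0.06. Longer handling of the mutant embryos stays open: the immediate early list had a median of 0.12 (bootstrap interval -0.20 to 0.80) with members moving both ways. Low oxygen in the mutant embryos themselves may also underlie the rise and was not tested.

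The fall of neuron genes was weighed against scaling and against a loss of neural tissue as a whole. The neuron median was -0.87 in the normalization where it lay nearest 0, normexp with quantile normalization, which falls short of the bound of -1.0 set beforehand for setting scaling aside. The offset of 50 units added there makes changes of dim genes smaller, since the median processed signal was only 45.0 to 65.9 units on the arrays. How much of the difference in the list median it accounts for was not tested. The list was called lower under each of the 6 normalizations. The median was -1.69 in the main values and -1.69 with median scaling. It was -1.59 after quantile normalization, -1.56 in the deposited value table and -1.27 under the planned normexp correction with 75th percentile scaling. These medians argue against scaling between arrays as the whole cause of the fall, although the bound set beforehand was not met. Neuron genes fell further than progenitor genes (median -0.62), by -1.08 (95% bootstrap interval -1.72 to -0.25), but the interval reaches past the limit of -0.5, so a general loss of neural tissue cannot be told apart from a loss of neurons. A change of neurogenesis with genotype was not tested. Nor was a difference in stage between the pools within embryonic day 9.5, so the falls here cannot be told apart from one.

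The call of the ribosomal protein list is consistent with technical explanations. Its median lay at percentile 92.9 among 10000 random lists of equally bright genes, whose median was 0.16, so that bright genes in general read slightly higher in the Arid3b-null arrays. Under the other normalizations the median ranged from -0.064 to 0.52. Whether ribosomal protein genes also change with genotype was not tested further.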
